A study of Nicotiana attenuata with 9 samples.

How the data were processed

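The series measured gene expression in leaves of Nicotiana attenuata, a wild tobacco, 1 h after wounding and application of 20 µL of diluted oral secretions of Manduca sexta larvae. The 9 samples fall into 3 groups of 3: wild type, and transgenic lines named irDCL3 and irDCL4 after the Dicer-like genes that their inverted-repeat constructs target. Groups and replicate numbers were taken from the sample titles. The series' design text describes the replicates of each genotype as independent experiments, and p-values measure only the spread between these arrays. Each sample was labelled with Cy3 and hybridised to its own array, per the labels' protocols, and the spots carry a design of 43533 different non-control probes in 43803 spots.

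The deposited scanner files give a spot's brightness as an intensity on a linear scale, with a spatially detrended background and a multiplicative detrend within each array by Feature Extraction and surrogate values for spots not above background, per the file headers. The submitters' processing notes name Agilent Feature Extraction version 9.5, while the file headers give 9.1.1.1. No normalization between arrays is recorded in the headers. The authors' deposited value table holds a processed intensity per probe. In 8 of its 9 columns, 100% of the values equalled the array's own processed signal divided by its 75th percentile over all spots, within a relative tolerance of 1e-04. Its scale is therefore linear, with no centring of genes and no ratio direction to settle, and how the table was made is not given in the sources used here. The column medians were 0.105, 0.110 and 0.106 for wild type, 0.117, 0.107 and 0.116 for irDCL3, and 0.105, 0.103 and 0.106 for irDCL4. The column of irDCL4 replicate 1 did not hold that array's values: 100% of it equalled the mean of replicates 2 and 3, and its correlation across probes with its own scanner file was 0.891 on the log2 scale. The scanner files were therefore used throughout. The deposited values served only as alternatives, without that column because of its mismatch and, chosen after the mismatch was seen, with it.

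For each array, spots of a probe were averaged, log2 was taken and the array's 75th percentile over non-control probes was subtracted. Spots marked as non-uniform or as population outliers were first treated as missing (302 probe values on all arrays together, 146 of them among the probes kept). No spot was saturated. Probes were kept where the scanner software called them well above background on all 3 arrays of at least 1 group, which kept 24296 probes and left out 19237. Of the probes kept, 20152 carry the entry name of a similar protein, often from another species, as the array design gives it, and 4144 carry only a contig identifier. No genome was used here, so probes have no coordinates. Names are given as in the files and state a similarity, not an established identity.

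A linear model with 1 mean per group was fitted over all 9 arrays with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), with a two-sided moderated test, 6 residual and 2.78 prior degrees of freedom, and Benjamini-Hochberg adjustment over the 24296 probes. The threshold was an adjusted p of 0.05. The comparisons were each line against wild type, irDCL4 against irDCL3, and the mean of both lines against wild type. Every ± beside a log2 difference is the standard error of this fit, with n = 3 arrays per group, unless an alternative fit is named. There it is the standard error of that fit, on the arrays that it holds. Where a probe was not well above background on any array of a group, the difference is given as "at least N-fold": the brighter group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

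The probes of 31 gene lists, on RNA silencing, defence, hormones, metabolism and housekeeping, were tested on the 24150 probes with no missing value with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry beside it. The list themes, the comparisons, the thresholds, the alternatives and the rule for named genes were set before the data were examined. Because the array names its probes by protein entry names, the themes were translated into entry-name patterns after the names, but not the comparisons, had been seen. Named genes are every Dicer-like probe above background in at least 1 group; for each line against wild type the 10 highest and 10 lowest non-overlapping changes past the threshold with an informative name; for irDCL4 against irDCL3 the 5 highest and 5 lowest; and up to 4 members with the smallest p in each list described, with 1 probe per gene. Among the genes this rule names, 1 is not reported here, nor are the list counts and fry results that rest on it. Entries named only by a locus were treated as uninformative after the calls were seen. The lists described in detail, and PER4_ARATH, CML41_ARATH, PTR5_ARATH, AGP19_ARATH, CNBL1_ARATH, SCS_SALOF, ASNS_ORYSJ between the lines, and the contigs, were chosen after their values were seen.

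Alternatives covered background correction (normexp with offset 50), scaling, the filter on dim probes, the replicate number, slide and scan date as blocks, the arrays in the fit, the variance model, array weights, thresholds, the deposited values, outlier spots and leaving out each array. On simulated data for irDCL3 against wild type over 24296 probes, 20% of 100 probes changed by log2 1 were recovered, 86% of 100 changed by log2 2, and 5 of 24096 unchanged probes were called. On simulated data for irDCL4 against wild type, a list shifted by log2 0.5 was called at an adjusted p of 4.65e-27 with the preset and 0.000244 with an estimated correlation, and 0 of 30 other lists were called. Simulated probes were drawn independently of each other, so these calls do not show how camera with its preset correlation fares for correlated lists. In the data the estimated correlation of the ribosomal list was 0.792. The number of arrays limits the precision. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.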

Results

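Leaf transcripts of wild-type Nicotiana attenuata and of the lines irDCL3 and irDCL4 were compared 1 h after elicitation with Manduca sexta oral secretions, on 3 arrays per genotype. Dicer-like proteins are the ribonucleases that cut double-stranded RNA into small RNAs. Between 52% and 59.9% of probes were well above background on 8 of the arrays. On irDCL4 replicate 1 the share was 85.8%, its median processed signal was 41.92 against 8.78 to 16.68 on the others, and 295 of its spots were marked as non-uniform against 0 to 3. The median correlation of this array with the others was 0.944 across probes, compared with 0.968 to 0.984 for the rest. Wild-type replicates 1 and 2 were scanned on the earlier of 2 dates, and wild-type replicate 3 and all arrays of both lines on the later one. In a fit with scan date as a block, each line's difference from wild type therefore rests on wild-type replicate 3 alone. The 9 arrays lay on 7 slides. Wild-type replicate 3 shared a slide with irDCL4 replicate 2, and irDCL3 replicate 1 shared one with irDCL4 replicate 3.

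The targeted genes check the labels of the lines. The probe named DCL4_ORYSJ was lower on the arrays labelled irDCL3, with log2 values of -3.93, -4.44 and -4.38 against -2.72, -2.72 and -2.91 in wild type. On the arrays labelled irDCL4 it read -1.02, -2.61 and -3.47. The log2 difference of DCL4_ORYSJ from wild type was -1.47 ± 0.51 for irDCL3 (adjusted p = 0.643, limma) and 0.41 ± 0.51 for irDCL4 (adjusted p = 0.785), the latter turning to -0.09 with normexp background correction and -0.06 with median scaling. This probe was well above background on 1 of 3 irDCL3 arrays. Without irDCL4 replicate 1, the differences were -1.47 ± 0.24 (adjusted p = 0.0604) and -0.26 ± 0.27 (adjusted p = 0.870). The 3 probes named DCL3A_ORYSJ differed from wild type by -0.09 ± 0.13, 0.06 ± 0.17 and -0.09 ± 0.20 on the arrays labelled irDCL3. On those labelled irDCL4 the same DCL3A_ORYSJ probes differed by -0.35 ± 0.13, -0.24 ± 0.17 and -0.53 ± 0.20, with adjusted p from 0.502 to 0.672. The 2 probes named DCL2B_ORYSJ differed by 0.10 ± 0.36 and -0.17 ± 0.22 in irDCL3, and by 0.16 ± 0.36 and -0.41 ± 0.22 in irDCL4. Between the lines the DCL4_ORYSJ probe differed by 1.88 ± 0.51 (adjusted p = 0.580), irDCL4 minus irDCL3. By limma, 0 of the 6 Dicer-like probes above background passed the threshold in any comparison, and 1, 2 and 1 had an unadjusted p under 0.05 in irDCL3, in irDCL4 and between the lines. Adjusted over the list alone, 1 was higher in irDCL4 than in irDCL3 and 0 differed between either line and wild type. Under other settings the DCL4_ORYSJ probe did pass as lower on the arrays labelled irDCL3, at -1.47 ± 0.18 with only these arrays and wild type in the fit (adjusted p = 0.0357), within a range of adjusted p from 0.022 to 1 over its alternatives. The 0.022 came from the deposited values with the column of irDCL4 replicate 1 taken as an array. That column is the mean of replicates 2 and 3 and no independent array, so this value is no support. Whether a probe lies in a silencing fragment is not given in the sources used here, so the directions go against the labels without settling them. The lines are therefore called "the arrays labelled irDCL3" and "the arrays labelled irDCL4".

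**Figure D1:**
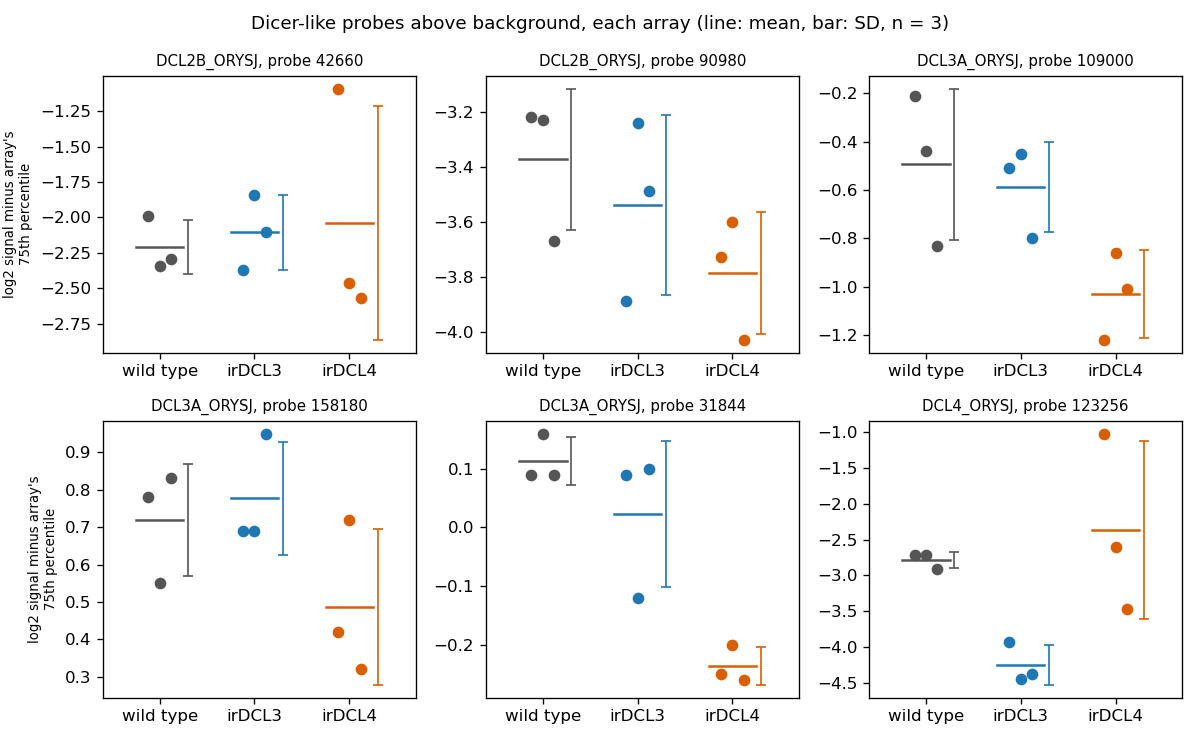
Each panel plots 1 Dicer-like probe well above background: log2 signal minus the array's 75th percentile for each array (points), the group mean (line) and its SD (bar, n = 3). The DCL4_ORYSJ probe is lowest on the arrays labelled irDCL3 (-3.93 to -4.44), and 2 of the 3 DCL3A_ORYSJ probes are lowest on all arrays labelled irDCL4 (-0.20 to -0.26 and -0.86 to -1.22).

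The comparison of irDCL3 with wild type asks which transcripts of the elicited leaf differ between the arrays with these labels. On the arrays labelled irDCL3, 67 probes passed the threshold, 63 of them higher than in wild type and 4 lower. Among the higher ones RIN4_ARATH, a regulator of plant immune receptors, rose by log2 2.68 ± 0.36 (adjusted p = 0.0248), and the transcription factor WRK20_ARATH rose by 1.88 ± 0.17 (adjusted p = 0.00484). The peroxidase PER4_ARATH rose by 1.45 ± 0.16 and the calmodulin-like CML41_ARATH by 1.28 ± 0.20. ASNS_ORYSJ, an asparagine synthetase that stores nitrogen in amide form, fell by 1.67 ± 0.19 (adjusted p = 0.0109). In the jasmonate pathway OPRL1_ARATH, similar to 12-oxophytodienoate reductase, fell by at least 1.71-fold (adjusted p = 0.0174), as it was not well above background on the irDCL3 arrays. None of the other probes named OPRL1_ARATH passed. Of the 9 kept probes named RIN4_ARATH and the 2 named WRK20_ARATH, only the 1 given for each passed.

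Other named probes that rose on the arrays labelled irDCL3 mostly carry names from distant species. PCF11_HUMAN, a pre-mRNA cleavage factor, was not well above background in wild type and rose at least 5.20-fold (adjusted p = 0.00284). S35D2_MOUSE, a nucleotide-sugar transporter, rose by log2 2.68 ± 0.19 (adjusted p = 0.0018), and 7OMT9_MEDSA, an O-methyltransferase, by 2.17 ± 0.32. The remaining ones were ETF2_YMTV (2.42 ± 0.34), INSI1_DANRE (2.37 ± 0.34), PXR1_LODEL (2.25 ± 0.30), RCDK_DICDI (2.19 ± 0.18) and HDA22_DICDI (1.86 ± 0.25), with ETF2_YMTV well above background on 2 of 3 wild-type arrays. The peptide transporter PTR5_ARATH rose by 1.03 ± 0.16, and NMNA2_RAT fell by 1.34 ± 0.20. Only 1 of 20 kept probes named PTR5_ARATH, 1 of 7 named PXR1_LODEL and 1 of 2 each named S35D2_MOUSE and 7OMT9_MEDSA passed. All 67 probes had non-overlapping groups, as did 15.7% of all probes, where chance gives 10% for 3 arrays against 3. Contig identifiers alone named 35 of the 67. Scan date as a block left 15 probes past the threshold, 12 of them among the 67, and RIN4_ARATH (2.42 ± 0.52), WRK20_ARATH (1.83 ± 0.26), PER4_ARATH (1.35 ± 0.24) and ASNS_ORYSJ (-1.87 ± 0.26) were not among them, with larger standard errors than without the block. Within the later date the 67 probes had a median absolute difference of 1.92, against 1.86 over all arrays, which is no test of the date, as the probes were called with wild-type replicate 3 included. An unadjusted p under 0.05 was reached by 1492 probes, against 1215 expected by chance. It was reached by 1224 with scan date as a block, 506 under median scaling and 2092 with slide as a random block.

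The gene lists described the arrays labelled irDCL3 as follows. Of 60 WRKY probes, 1 rose (WRK20_ARATH) and 59 did not pass, and the count adjusted over the list alone was also 1. The WRKY list median was 0.25 (camera adjusted p = 1.72e-05; adjusted p = 0.815 with an estimated correlation). WRK46_ARATH gave 0.57 ± 0.22 and WRK64_ARATH 0.55 ± 0.21. With scan date as a block the WRKY median was 0.07 (adjusted p = 0.125), and wild-type replicate 3 exceeded the earlier wild-type arrays by a median of 0.20 over these probes. Within the later date the irDCL3 arrays exceeded wild-type replicate 3 by a median of 0.07, which is the same estimate as that with the block. Of 111 reactive oxygen probes 1 rose (PER4_ARATH), and of 186 calcium probes 1 rose (CML41_ARATH). Adjusted over the list alone these counts were 1 and 2. Fry found no list moving 1 way (lowest adjusted p = 0.852), and its test for change in either direction gave 0.037 for transposable elements.

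Camera with its preset correlation called the ribosomal, photosynthesis and pentatricopeptide lists lower and the senescence list higher on the arrays labelled irDCL3. With an estimated correlation none of these calls held, each at an adjusted p of 0.815. By limma 0 ribosomal or photosynthesis probes passed, over all probes or adjusted over the list alone. An unadjusted p under 0.05 was reached by 0 ribosomal probes, and by 3 higher and 5 lower photosynthesis probes. The 205 ribosomal protein probes had a median of -0.30 (camera adjusted p = 2.99e-09), and RS172_ARATH read -0.61 ± 0.29. The 147 photosynthesis probes had a median of -0.19 (adjusted p = 1.2e-06), with Rubisco activase RCA_SOLPN at -0.48 ± 0.15, although the carbonic anhydrases CAHC_TOBAC and CAHC_SPIOL were at 2.07 ± 0.46 and 1.80 ± 0.41. The 160 pentatricopeptide repeat probes had a median of -0.19 (adjusted p = 0.00222), with 0 past over all probes, 3 higher and 10 lower at an unadjusted p under 0.05, and 1 higher adjusted over the list alone (PP187_ARATH, 1.29 ± 0.22). The 54 senescence and autophagy probes had a median of 0.14 (adjusted p = 0.0108), with 0 past either way, 2 at an unadjusted p under 0.05, and the autophagy gene ATG8C_ORYSJ at 0.46 ± 0.15. Without irDCL3 replicate 3 the ribosomal median was 0.06 (adjusted p = 0.0946), that of the pentatricopeptide list -0.01 (adjusted p = 0.977), that of WRKY 0.05 (adjusted p = 0.444) and that of senescence 0.07 (adjusted p = 0.529), or 0.10 without wild-type replicate 3 (adjusted p = 0.0604) and 0.06 under median scaling (adjusted p = 0.254), but 0.28 with scan date as a block (adjusted p = 0.00502). The pentatricopeptide median was -0.13 with scan date as a block (adjusted p = 0.0983) and -0.17 with no filter on dim probes (adjusted p = 0.0532). Under quantile normalization the photosynthesis median was -0.05 (adjusted p = 0.282). The 26 lists not called had medians from -0.09 to 0.17 and adjusted p from 0.0551 to 0.911.

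**Figure D2:**
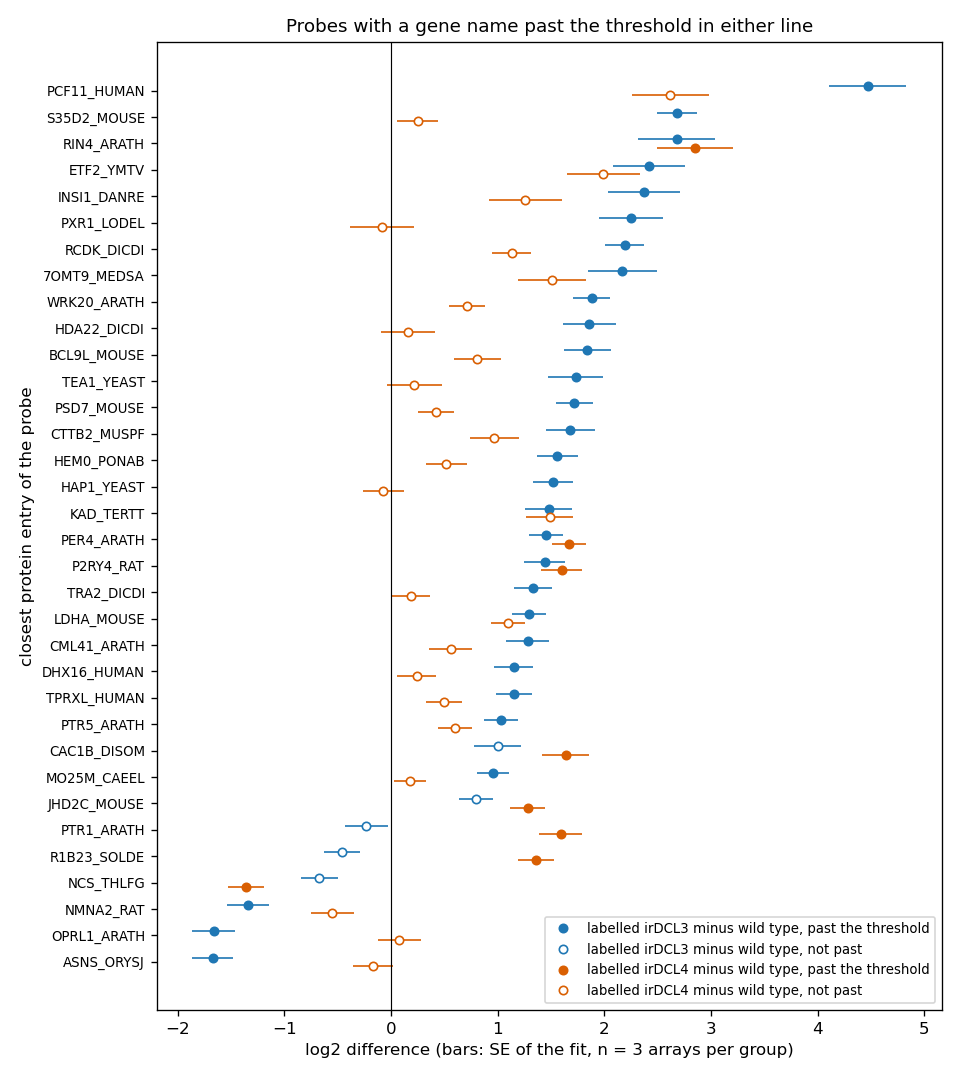
The plot shows the log2 difference from wild type (x axis) of each probe with an informative name that passed the threshold in either line, except 1 not reported here; bars are the SE of the fit (n = 3 arrays per group), filled points passed the threshold and open points did not. RIN4_ARATH stands at 2.68 and 2.85 in the lines labelled irDCL3 and irDCL4, while S35D2_MOUSE stands at 2.68 in the former and differed between the lines by -2.43 ± 0.19 (irDCL4 minus irDCL3).

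The comparison of irDCL4 with wild type asks the same for the arrays with the irDCL4 label. On the arrays labelled irDCL4, 21 probes passed, 19 higher and 2 lower. RIN4_ARATH rose by log2 2.85 ± 0.36 (adjusted p = 0.038) and PER4_ARATH by 1.67 ± 0.16 (adjusted p = 0.0174), as in the other line. The nitrate and peptide transporter family member PTR1_ARATH rose by 1.59 ± 0.20 (adjusted p = 0.038), and R1B23_SOLDE, a late blight resistance protein homologue of the NBS-LRR class, by 1.36 ± 0.17 (adjusted p = 0.038). Only 1 of 9 kept probes named RIN4_ARATH, 1 of 20 named PTR1_ARATH and 1 of 5 named R1B23_SOLDE passed. NCS_THLFG, named after an enzyme of benzylisoquinoline alkaloid synthesis, fell by 1.36 ± 0.17 (adjusted p = 0.038).

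Further named probes moved too. CAC1B_DISOM rose by 1.64 ± 0.22, P2RY4_RAT by 1.60 ± 0.19 and the demethylase-like JHD2C_MOUSE by 1.28 ± 0.16. Contig identifiers alone named 10 of the 21. The contigs Na_454_31426 and Na_454_20832 were not well above background on any wild-type array and were on all arrays of both lines, at least 14.3-fold and 9.11-fold higher on the arrays labelled irDCL4 and at least 8.87-fold and 8.60-fold higher on those labelled irDCL3. The contig Na_454_32880 was lower by log2 3.64 (-3.64 ± 0.41, adjusted p = 0.0319), and was well above background on 1 of 3 irDCL4 arrays. All 21 probes had non-overlapping groups, as did 19.1% of all probes. Quantile normalization left 4 probes and scan date as a block 5, of which 4 and 3 were among the 21. With the date as a block RIN4_ARATH was at 2.59 ± 0.52, and within the later date the 21 probes had a median absolute difference of 2.59, against 2.65 over all arrays, again with wild-type replicate 3 among the arrays that selected them. Leaving out irDCL4 replicate 1 gave 13, of which 11 were among the 21. By limma 2161 probes reached an unadjusted p under 0.05 against 1215 expected by chance. That number depended on the setting, with 1346 for scan date as a block, 1201 under median scaling and 3959 for slide as a random block.

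Among the gene lists on the arrays labelled irDCL4, photosynthesis had the lowest camera p. Of its 147 probes 0 passed by limma, over all probes or adjusted over the list alone, and the median was -0.31 (camera adjusted p = 1.45e-18; adjusted p = 0.736 with an estimated correlation). The Rubisco small subunit RBS_TOBAC was at -0.72 ± 0.17 and RCA_SOLPN at -0.68 ± 0.15, while CAHC_TOBAC was at 1.76 ± 0.46. An unadjusted p under 0.05 was reached by 41 lower and 3 higher probes (limma). The photosynthesis median was -0.35 with scan date as a block, and -0.35 on the slide shared by wild-type replicate 3 and irDCL4 replicate 2. Both values rest on that same wild-type array. Under quantile normalization the median was -0.07 (camera adjusted p = 0.246). The 205 ribosomal protein probes had a median of -0.29 (camera adjusted p = 2.29e-09; adjusted p = 0.765 with an estimated correlation), with 0 past over all probes or adjusted over the list alone and 2 at an unadjusted p under 0.05 (limma), and normexp background correction gave -0.11 (adjusted p = 0.3), and the median was -0.13 without irDCL4 replicate 1 and with scan date as a block (adjusted p = 0.13).

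Camera with its preset correlation called the WRKY and phenylpropanoid lists higher on the arrays labelled irDCL4, and neither call held with an estimated correlation (adjusted p = 0.765 for each). The lists of NBS-LRR, reactive oxygen, pathogenesis-related and proteinase inhibitor probes were not called by camera with either correlation. Fry found no list moving 1 way (lowest adjusted p = 0.228), and its test for change in either direction, which does not compare a list with other genes, gave an adjusted p of 0.00354 for NBS-LRR, 0.00371 for reactive oxygen, 0.0161 for photosynthesis and 0.0443 for WRKY probes. Of 60 WRKY probes 0 passed over all probes by limma, 14 had an unadjusted p under 0.05 and 6 were higher adjusted over the list alone, with a median of 0.27 (camera adjusted p = 4.27e-05; adjusted p = 0.765 with an estimated correlation). WRK46_ARATH was at 1.58 ± 0.22 (adjusted p = 0.057), WRK20_ARATH at 0.71 ± 0.17 and WRK64_ARATH at 0.88 ± 0.21. With scan date as a block the WRKY median was 0.14 (camera adjusted p = 0.0949), and the median within the later date, 0.14, is the same estimate. Of 97 phenylpropanoid probes 0 passed over all probes by limma, 10 higher and 2 lower had an unadjusted p under 0.05 and 1 was higher adjusted over the list alone, with CHS2_SOLTU, a chalcone synthase at the entry to flavonoids, at 1.12 ± 0.20 and CAMT5_TOBAC, a caffeoyl-CoA O-methyltransferase, at 1.01 ± 0.25. The phenylpropanoid median was 0.18 (camera adjusted p = 0.0121; adjusted p = 0.765 with an estimated correlation), and 0.07 without wild-type replicate 3 (adjusted p = 0.197) or 0.15 without irDCL4 replicate 3 (adjusted p = 0.196). It was 0.36 with scan date as a block (adjusted p = 5.46e-06), 0.32 with no filter on dim probes (adjusted p = 0.0489) and 0.02 under normexp background correction (adjusted p = 0.000107). Under median scaling the median of all probes shifted to -0.47, the WRKY and phenylpropanoid medians to -0.21 and -0.30, which lie 0.26 and 0.17 above it. Of 40 NBS-LRR probes 1 rose over all probes (R1B23_SOLDE) and 2 adjusted over the list alone. Of 111 reactive oxygen probes 1 rose (PER4_ARATH) and 4 adjusted over the list alone, with the glutathione S-transferase GSTX4_TOBAC at 3.63 ± 0.75, well above background on 1 of 3 wild-type arrays. The 27 lists not called had medians from -0.29 to 0.25 and camera adjusted p from 0.0555 to 0.863.

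**Figure D3:**
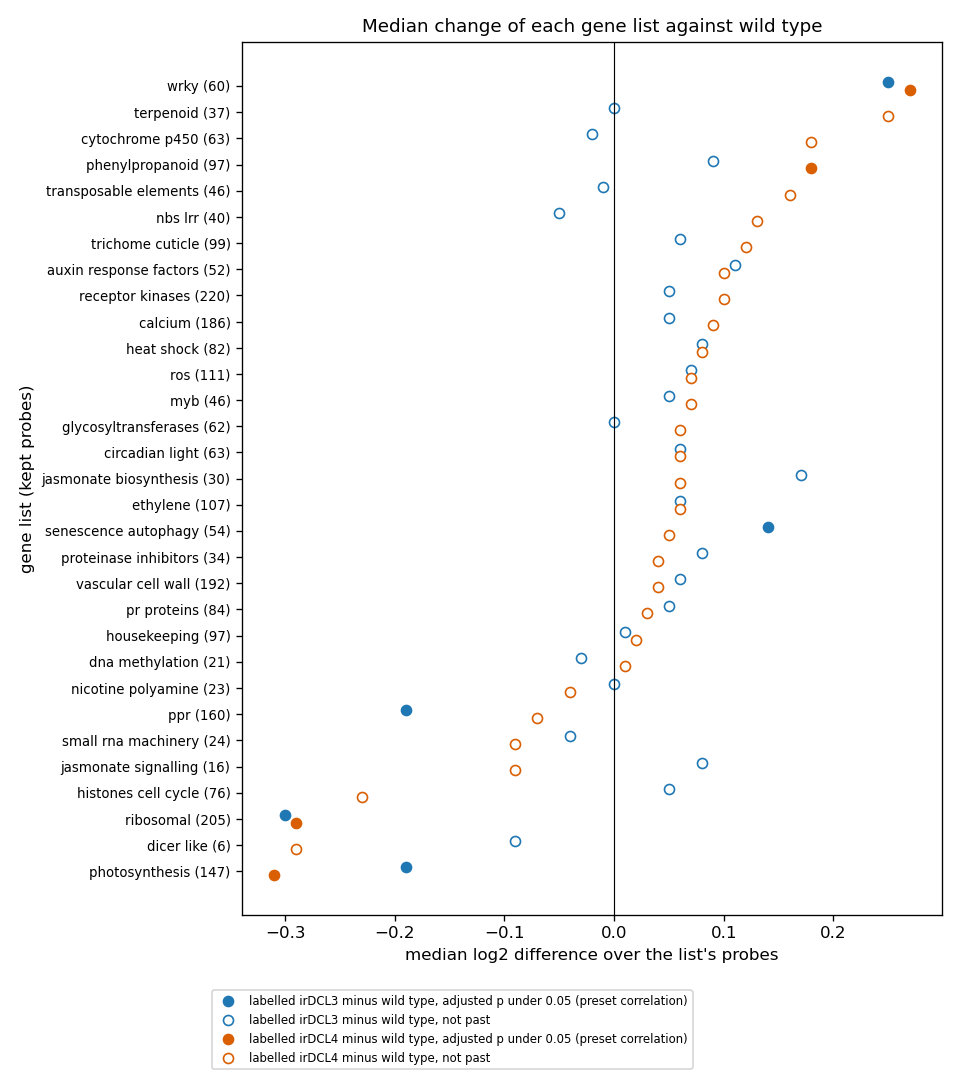
Each point is the median log2 difference from wild type over the kept probes of a gene list (number in brackets), for the arrays labelled irDCL3 and irDCL4; filled points had an adjusted p under 0.05 by camera with its preset correlation, and none did with an estimated one. Photosynthesis (-0.19 and -0.31) and ribosomal proteins (-0.30 and -0.29) lie below 0 and WRKY (0.25 and 0.27) above it, with WRKY at -0.21 in irDCL4 under median scaling, where all probes shift to -0.47.

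Both lines were set against wild type together. The 2 lines shared 8 probes past the threshold, all higher in both, out of a union of 80. RIN4_ARATH, PER4_ARATH, P2RY4_RAT and the contigs Na_454_31426 and Na_454_20832 were among them. Independent lists of 63 and 19 higher probes would share 0.0493. Unchanged groups simulated as independent noise, with the simulated wild-type arrays common to both lines, shared 0 in 100 draws. That 0 is no test of the shared calls, as such noise holds no scan date, slide or correlation between probes. The log2 differences of the lines correlated across probes at 0.57, against 0.50 in the simulation, with a covariance of 0.0963 against 0.049, a difference of 0.0473. They had the same sign at 73.8% of probes, against 66.7%. The simulated values already hold what shared controls give under independent noise. With 3 wild-type arrays the controls could not be split, so part of the excess may still come from errors of the shared controls beyond such noise. Part may also come from the scan date, which sets wild-type replicates 1 and 2 apart from both lines. For the mean of both lines 58 probes passed, 57 higher and 1 lower. AGP19_ARATH, an arabinogalactan protein, rose by 2.41 ± 0.36 and SCS_SALOF, a monoterpene synthase, by 1.26 ± 0.19. Only 1 of 4 kept probes named AGP19_ARATH, well above background on 2 of 3 wild-type arrays, and 1 of 2 named SCS_SALOF passed. Of these 58 probes 56 had non-overlapping groups. Camera called 6 of 31 lists for the mean and 0 with an estimated correlation, where the lowest adjusted p was 0.713. Fry found no list moving 1 way for the mean (lowest adjusted p = 0.404), and in either direction an adjusted p of 0.0194 for reactive oxygen, 0.028 for photosynthesis, 0.028 for transposable elements and 0.0468 for WRKY probes. Scan date as a block gave 8 probes, of which 6 were among the 58. Within the later date the 58 had a median absolute difference of 1.69, against 1.55 over all arrays, but wild-type replicate 3 took part in selecting them. The series' design text gives 811 genes as regulated in these lines, and the criteria behind that number are not given in the sources used here.

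The direct comparison of irDCL4 with irDCL3 tests whether the lines differ from each other. It gave 28 probes, 12 higher and 16 lower on the arrays labelled irDCL4. ASNS_ORYSJ was higher there by log2 1.5 ± 0.19 (adjusted p = 0.0314), and OPRL1_ARATH by at least 1.80-fold (adjusted p = 0.0287). R1B23_SOLDE was higher by 1.82 ± 0.17, PTR1_ARATH by 1.82 ± 0.20 and NGDN_HUMAN by 2.12 ± 0.26. The differences were -2.43 ± 0.19 for S35D2_MOUSE, -2.33 ± 0.30 for PXR1_LODEL, -2.17 ± 0.25 for the transporter PTR3A_ARATH, -1.70 ± 0.22 for the pentatricopeptide repeat protein PP187_ARATH and -1.59 ± 0.19 for HAP1_YEAST. Only 1 of 20 kept probes named PTR1_ARATH, 1 of 5 each named R1B23_SOLDE and OPRL1_ARATH, 1 of 7 each named PXR1_LODEL and PTR3A_ARATH and 1 of 2 named S35D2_MOUSE passed. Of the 59 probes called only on the arrays labelled irDCL3, 14 passed between the lines, as did 5 of the 13 called only on those labelled irDCL4. All 28 had non-overlapping groups, as did 7.5% of all probes. An unadjusted p under 0.05 was reached by 1191 probes, against 1215 expected by chance. The split by direction depended on single arrays, with 41 higher and 12 lower without irDCL4 replicate 2, 23 and 6 without irDCL4 replicate 3, and 9 and 21 without irDCL4 replicate 1. Normexp background correction gave 8 higher and 34 lower and scan date as a block 6 and 5. With only these 2 groups in the fit, or with no filter on dim probes, 0 probes passed.

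Between the lines, the 16 jasmonate signalling probes had a median of -0.19 (camera adjusted p = 0.00744; adjusted p = 0.341 with an estimated correlation), with the TIFY family member TIF4B_ARATH at -0.73 ± 0.27. It was -0.14 without irDCL3 replicate 3 (adjusted p = 0.0737) and -0.12 without irDCL4 replicate 2 (adjusted p = 0.0781). The 63 cytochrome P450 probes had a median of 0.18 (adjusted p = 0.00942; adjusted p = 0.357 with an estimated correlation), which was -0.03 under normexp background correction, and 0.16 without irDCL3 replicate 2 or irDCL4 replicate 3 (adjusted p = 0.0857 and 0.0769). Under median scaling it was -0.22, 0.16 above the shift of all probes to -0.38. The 76 histone and cell cycle probes had a median of -0.29 (adjusted p = 0.00096; adjusted p = 0.930 with an estimated correlation), and 0.01 without irDCL3 replicate 1 (adjusted p = 0.857), -0.17 without irDCL3 replicate 2 (adjusted p = 0.0717) and -0.10 without irDCL4 replicate 2 (adjusted p = 0.272). The photosynthesis median was -0.15 (adjusted p = 7.01e-08; adjusted p = 0.902 with an estimated correlation), -0.09 without irDCL4 replicate 1 (adjusted p = 0.0517), and 0.09 within the slide that holds both lines. By limma 0 probes of these 4 lists passed, over all probes or adjusted over the list alone, and 1, 7, 1 and 3 had an unadjusted p under 0.05 in the order given. None of the 4 was called under normexp background correction, with adjusted p of 0.0903 for jasmonate signalling, 0.391 for cytochrome P450, 0.0983 for histones and 0.743 for photosynthesis, or under quantile normalization, with 0.0914, 0.147, 0.0914 and 0.879. Fry found no list moving 1 way between the lines (lowest adjusted p = 0.38), and in either direction an adjusted p of 8.1e-05 for NBS-LRR probes. The 27 lists not called had camera adjusted p from 0.0729 to 0.853.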

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

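The tests on the label exchange, on irDCL4 replicate 1 for the DCL4_ORYSJ probe and for the share of higher calls, on scaling, and on quantile normalization of the photosynthesis list were chosen after the result was seen. A first scan-date test of the higher calls was replaced after it was run, because its outcome was fixed by the way the probes had been selected.

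A difference between the lines marked 28 probes, tested directly as irDCL4 minus irDCL3. By name these included NGDN_HUMAN (2.12), R1B23_SOLDE (1.82) and PTR1_ARATH (1.82) on the higher side, and S35D2_MOUSE (-2.43), PXR1_LODEL (-2.33), PTR3A_ARATH (-2.17), PP187_ARATH (-1.70) and HAP1_YEAST (-1.59) on the lower side, all log2. OPRL1_ARATH was fitted at 1.73, but as it was not well above background on any irDCL3 array the values support only at least 1.80-fold.

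The DCL4_ORYSJ probe was lower on the arrays labelled irDCL3, and the DCL3A_ORYSJ probes were not. The array irDCL4 replicate 1 takes no part in the size of these differences between irDCL3 and wild type. Without it the DCL4_ORYSJ probe was still higher by 1.21 ± 0.27 on the arrays labelled irDCL4 than on those labelled irDCL3. The low irDCL3 values alone can give such a gap, so this is no test of an effect of that array. An exchange of the lines' labels stays open: the median difference of the DCL3A_ORYSJ probes on the arrays labelled irDCL4 was -0.35, in the direction an exchange needs, but their smallest p adjusted over the Dicer-like probes alone was 0.0768. It cannot be told apart from probes that do not report the targeted transcript, because the silencing fragments are not given in the sources used here.

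The photosynthesis list was called lower on the arrays labelled irDCL4 by camera with its preset correlation (median -0.31), but not with an estimated correlation (adjusted p = 0.736), and by limma 0 of its 147 probes passed, over all probes or adjusted over the list alone, with 41 lower and 3 higher at an unadjusted p under 0.05. Without irDCL4 replicate 1 the median was -0.23 (89.1% of probes below 0), which argues against that array as the whole cause. With scan date as a block it was -0.35 (88.4%). That goes against scan date as the whole cause, but only by comparison with 1 wild-type array, replicate 3. Probes of the same brightness also fell, with a median of -0.16 over 10000 matched random lists, and the list lay at percentile 0 of them, though such lists lack the correlation between photosynthesis genes. Quantile normalization left -0.07, but the list holds 32.0% of the 200 brightest probes, which that method sets equal between arrays, and those of the 200 in neither the photosynthesis nor the ribosomal list had a median of -0.27. A difference of the arrays at high signal therefore cannot be told apart from a change of the genes, and an effect of the line stays a hypothesis.

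Probes past the threshold were nearly all higher in the lines than in wild type, but not under each alternative: within the later scan date and without irDCL4 replicate 1, where a single wild-type array remains, 16 were higher and 29 lower for the mean of both lines, 27 and 22 for irDCL3, and 6 and 24 for irDCL4. Each difference there rests on that 1 wild-type array, and why the direction turned was not tested. The scaling and irDCL4 replicate 1 are argued against by the shares of higher calls for the mean of both lines, which were 95.6% at the lowest of the quantile and median scalings and 100% without that array. Scan date stays open: in a fit without wild-type replicate 3, that array lay a median of 8.20% of the way from the earlier wild-type arrays to the lines over 10 probes, with a range from -85.2% to 51.0%. With scan date as a block, 8 probes were higher and 0 lower for the mean. The split was 15 and 0 for irDCL3 and 5 and 0 for irDCL4, each against wild-type replicate 3 alone. A biological effect of the constructs is likewise open.

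Other groupings of the same arrays were counted. For irDCL3 against wild type, irDCL4 against wild type and irDCL4 against irDCL3 the 10 splits are too few for a share under 0.05, with 67, 21 and 28 probes for the real grouping and 0 for the highest other, so 1 of 10 splits gave as many. For the mean of both lines, 1 of 100 splits gave 58 probes or more, the real one. The highest other, which keeps the irDCL3 arrays together, gave 20. Chance is not excluded for that count, as the 100 are a sample of the possible splits. The probes were also kept by the real groups, which favours the real grouping here and among the 10 splits. For the mean, the real grouping gave 3 probes with no filter and 48 with only probes above background on all 9 arrays. Other splits were not counted under these filters. The count also fell below 20 under some alternatives, to 3 without irDCL3 replicate 2 and to 8 with scan date as a block.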

How the results depend on the processing

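The alternatives were listed before the data were examined, except those that join irDCL4 replicate 1, the later scan date and scan-date block, and the value table with the repeated column taken as an array, which were chosen after seeing the data. Leaving the repeated column out of the value table also rests on its mismatch with the scanner file. The named genes past the threshold kept their direction in 99.9% of 1191 combinations with an alternative. Of the combinations, 658 stayed past the threshold, 532 did not, and 1 turned, OPRL1_ARATH between the lines at -0.03 with normexp. The kept direction is little evidence, as probes called with non-overlapping groups cannot turn when an array is left out. Of these 43 named calls, 0 stayed past the threshold under each alternative. The gene each line is named after gave 0 calls as lower in that line under each alternative. The DCL4_ORYSJ probe, which does not pass in the planned fit, passed as lower on the arrays labelled irDCL3 with only the 2 groups in the fit (-1.47, adjusted p = 0.0357) and with the repeated column taken as an array (-1.47, adjusted p = 0.022). The repeated column is no independent array, as it equals the mean of irDCL4 replicates 2 and 3, and it lowers the spread within that group. The cause of the other differences was not tested. Counts below are for irDCL3, irDCL4, the difference between lines and the mean, against 67, 21, 28 and 58. Normexp gave 36 for the mean and 23 called lists against 13. Quantile normalization gave 44, 4 and 24 (irDCL3, irDCL4, mean), and median scaling 44 for irDCL4 and 56 between lines, with 34 and 18 of them higher. Between lines quantile normalization had 7 higher and 16 lower. No filter gave 7, 3, 0 and 3 by limma, with the 43533 probes unfiltered. Between lines 998 probes had an unadjusted p under 0.05, fewer than the 1215 that chance gives for only 24296 probes. Probes above background on all 9 arrays gave 11 for irDCL4 and 21 lists. Slide as a random block gave 161, 90 and 107 (irDCL4, between lines, mean), with a consensus correlation of 0.646. Scan date as a block gave 15, 5, 11 and 8. Fits of only the 2 groups compared gave 5 for irDCL4 and 0 between lines, where 781 had such a p. Trend and robust gave 58 and 43 for the same. Array weights gave 227, 71, 63 and 192, with the lowest weights, 0.27 and 0.31, on irDCL4 replicate 1 and irDCL3 replicate 3. An adjusted p under 0.01 gave 21, 3, 3 and 7. The value table without the repeated column gave 103 and 13, and with it taken as an array 223, 126, 130 and 170, and 22 lists. Without irDCL4 replicate 1 and with scan date as a block, irDCL4 gave 1, the difference 18 and the mean 18. The later date alone, where the lone wild-type array is assumed to vary like the other groups, gave 0, 1, 0 and 1, with 948 and 776 at such a p for the counts of 0, and without irDCL4 replicate 1 it gave 49 (27 higher, 22 lower), 30 (6 higher, 24 lower), 9 (1 higher, 8 lower) and 45 (16 higher, 29 lower), so most calls for irDCL4 and for the mean were lower there. Of these, 16, 4, 3 and 7 were among the probes past the threshold with all arrays.

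Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.27 to 0.28, over 0.1 in 2 of 9 pairs. In both other groups at once, 0 arrays correlated best with their own number. Wild-type replicate 3 and irDCL3 replicate 3 did correlate best with each other (0.28). With the replicate number as a block the counts were 31, 12, 4 and 14.

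Leaving out 1 array at a time gave 14 to 103 probes for irDCL3, 3 to 35 for irDCL4, 3 to 53 between lines, 3 to 47 for the mean and 12 to 23 lists. For irDCL3 the count was 24, 25 and 24 without wild-type replicates 1, 2 and 3, 27 and 14 without irDCL3 replicates 1 and 2, and 103 and 41 without irDCL4 replicates 1 and 2. For irDCL4 it was 3, 5 and 6 without the wild-type arrays, 4 without irDCL3 replicate 2, and 13 and 35 without irDCL4 replicates 1 and 2. Between lines it was 10, 10 and 11 without the wild-type arrays, 4 and 3 without irDCL3 replicates 1 and 2, and 53 without irDCL4 replicate 2 (41 higher, 12 lower). For the mean it was 4, 8 and 10 without the wild-type arrays, 22 and 3 without irDCL3 replicates 1 and 2, and 12 and 25 without irDCL4 replicates 2 and 3. Called lists numbered 20 without wild-type replicate 2, and 21, 23 and 20 without irDCL3 replicates 1, 2 and 3.

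The 13 called list medians kept direction and threshold in 313 of 364 combinations, lost the threshold in 45 and turned in 6. Those that turned, with lists that passed only under an alternative, were as follows. With normexp cytochrome P450 between lines was -0.03 and transposable elements -0.12. Median scaling moved all probes to -0.10, -0.47 and -0.38 (irDCL3, irDCL4, between lines), and with it irDCL4 medians to -0.21 for WRKY, -0.30 for phenylpropanoid, -0.23 for terpenoid and -0.30 for cytochrome P450, and between lines to -0.29 for terpenoid and -0.22 for cytochrome P450, all above that shift. Leaving out arrays, the histone median ran from -0.21 (without irDCL3 replicate 1) to 0.48 (without irDCL3 replicate 3) for irDCL3, and from -0.70 (without irDCL3 replicate 3) to 0.01 (without irDCL3 replicate 1) between lines. The ribosomal median ran from -0.49 (without irDCL3 replicate 2) to 0.06 (without irDCL3 replicate 3) for irDCL3 and from -0.34 to 0.22 between lines (without irDCL3 replicates 3 and 2). For the same arrays the pentatricopeptide one ran from -0.08 to 0.18 between lines. Without irDCL4 replicate 3 the ribosomal median between lines was -0.09. Low signal over background limits probes near the floor. On irDCL4 replicate 1, 85.8% of probes counted as well above background.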

Other observations

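Anti-digestive proteinase inhibitors did not pass over all probes in either line. Of 34 probes, 2 rose on the arrays labelled irDCL4 and 0 on those labelled irDCL3 when adjusted over the list alone, with 4 and 3 at an unadjusted p under 0.05 (limma). IP23_CAPAN was not well above background in wild type and was at least 1.5-fold higher on the arrays labelled irDCL4 (limma adjusted p = 0.057), and the carboxypeptidase inhibitor MCPI_SOLTU was at 0.89 ± 0.18 there and 0.65 ± 0.18 on those labelled irDCL3. Transposon-like probes, targets of small-RNA silencing, had 2 of 46 higher in each line adjusted over the list alone and 0 over all probes, with 5 higher in each line at an unadjusted p under 0.05, and 0 and 2 lower in those labelled irDCL4 and irDCL3. M710_ARATH, well above background on 1 of 3 wild-type arrays, was at 1.63 ± 0.26 and 1.27 ± 0.26 in the lines labelled irDCL3 and irDCL4, and M240_ARATH at 0.59 ± 0.16 and 1.05 ± 0.16. The list medians were -0.01 and 0.16. Of 21 DNA methylation and demethylation probes, 1 fell in each line adjusted over the list alone, in both cases a demethylase-like DML3_ARATH probe but not the same one, at -0.85 ± 0.18 in irDCL3 and -0.64 ± 0.15 in irDCL4. The 24 other small-RNA machinery probes had medians of -0.04 and -0.09, with 0 past in either line by limma over all probes or adjusted over the list alone, and 0 and 1 at an unadjusted p under 0.05.

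In the calcium list CNBL1_ARATH, a calcineurin B-like sensor, was at 0.88 ± 0.16 and 1.02 ± 0.16 in the lines labelled irDCL3 and irDCL4. This is 1 of 5 kept probes of that name. The 23 nicotine and polyamine probes had medians of 0 and -0.04, and the 97 reference gene probes medians of 0.01 and 0.02.

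The authors' deposited value table holds, for irDCL4 replicate 1, the mean of the other irDCL4 columns. Taken as a separate array, that column gave 126 probes for irDCL4 against wild type, compared with 13 without it.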
